A study of Mus musculus and Homo sapiens with 80 samples.

How the data were processed

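Single-cell chromatin profiles made with antibody-tethered micrococcal nuclease were analysed from mouse bone marrow and from the human leukaemia line K562, for H3K4me1, H3K4me3, H3K27me3 and H3K9me3. Per the labels' protocols, marrow was flushed from femur and tibia, unnucleated cells were lysed, cells were incubated with antibody overnight and then with a protein A and nuclease fusion, and they were sorted into plates of 384 wells. The titles of the K562 samples carry the term G1, which is not explained in the sources used here. Per the submitters' processing notes, reads were mapped with BWA 0.7.16a, and mm10 is the build named. The human build is not given in the sources used here.

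The authors' deposited tables hold, for each cell, counts of nuclease cuts in windows of 100 kb that slide by 20 kb, with no normalization. The deposited B6 tables pool the 3 runs of each plate and hold estimated counts, since 105 entries per plate that have no coordinate carry multiples of 0.5, while every entry with a coordinate was whole. These entries held 5.45% to 13.66% of the counts of a B6 plate and were left out. Entries of the K562 tables that start below position 0 were left out. CPM was computed here from the counts, with library sizes scaled by the TMM factors of the fit for levels at windows, and without them for relations between marks, cluster names and shares of cuts.

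From the sliding windows a set that does not overlap (26498 in mouse, 29141 in human) was taken, so that each cut counted once. Wells with at least 500 cuts were kept, which left 10682 of 12287 marrow cells and 3747 of 4608 K562 cells. No doublet caller was run, since wells were sorted and the tables carry no transcript counts, so wells with more than 1 cell stay in. The highest number of cuts in a well was 293.7 times the 95th percentile of its library in K562 H3K27me3 replicate 2, and 15.6 times in 1 B6 H3K4me1 plate. Median cuts per cell ranged over plates from 2764 to 8787 (B6) and 2890 to 5651 (FVB) for H3K4me1, 2366 to 3487 and 1524 to 2471 for H3K4me3, 6083 to 21277 and 9655 to 15864 for H3K27me3, and 7459 to 14532 and 4216 to 8236 for H3K9me3. In K562 they ranged from 970 to 11132, 1487 to 2880, 7358 to 19181 and 10407 to 24103 in the same order of marks.

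Cells are not replicates, so cuts were summed per preparation and mark (12 libraries in marrow: FVB m1, FVB m2 and B6 m1 for 4 marks) and per replicate and mark in K562 (12 libraries). The labels do not say that the preparations are separate animals or the K562 replicates separate cultures, so p-values measure only the spread between these samples, which may be technical. Windows were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, low windows removed by filterByExpr, Benjamini-Hochberg adjusted p under 0.05), each mark against the mean of the other 3, and B6 against FVB within each mark. In the second of these comparisons B6 has 1 preparation, assumed to vary like the FVB preparations. Gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated one, and adjusted over the 18 lists of a contrast. The tests, lists, cell type markers and alternatives were fixed before the data were examined, except where the text says otherwise. In windows by mark, 66% to 73% of simulated changes of 2-fold were recovered in marrow and 1% to 6% in K562, and of 1.5-fold 3% to 11% and 0% to 1%. For B6 against FVB 89% to 99% and 23% to 95% were recovered, and for clusters 1% to 96% and 0% to 79%.

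Genes were placed in the window that holds the midpoint of the gene, since the annotation table used (GRCm38.p6, the assembly of mm10) gives no strand. The plan had named the transcription start. This placed 21887 genes in 11526 of the windows, and genes that share a window share its value. Without a human annotation K562 windows were given by coordinates, and the human lists were not used here. For each contrast the text draws on the 3 genes of each list (2 for lists under 12 genes) with the smallest adjusted p, and on the 5 windows with the largest and the 5 with the smallest fold among called windows with a mean of at least 20 CPM, named by up to 2 genes. Hbb-bs, S100a8, Ebf1, Hoxa9, Hoxd9, Sox6 and Gapdh were given for every mark. Some genes that this rule selects are not reported here. Coordinates are 1-based.

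For clustering, each cell's cuts were divided at random (binomial split, seed 1). The first part gave Pearson residuals of autosomal windows with at least 50 cuts against the window mean of the own preparation, 20 principal components without those whose Spearman correlation with the log total exceeded 0.5, 15 nearest neighbours and Leiden clusters at resolution 0.5. The other part was summed per cluster and preparation and tested with edgeR against the remaining cells, with preparation as a block, for clusters of at least 20 cells in every preparation. A name needed a list median of 0.5 (log2, windows of at least 20 CPM), a gap of 0.2 to the next list and at least 3 detected markers, and the first pair of these limits was set after the medians of the clustering part had been seen. On simulated cells without types 1 cluster was found, and with 3 types 3 clusters with an adjusted Rand index of 0.977. These simulated H3K4me3 alone (2429 cells), and clusters from technical differences were not tested.

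Concentration is the share of cuts in the 10% of windows with most cuts, with windows ranked on a random part of the cuts and the share measured on the rest after thinning to 1366671 cuts per marrow library and 241757 per K562 library. Cluster sums were thinned to 87558, 54708, 37603 and 251736 cuts for H3K4me1, H3K4me3, H3K27me3 and H3K9me3. Relations between marks are Spearman rho across windows of log2 (CPM + 1), and windows are not independent replicates. Shares of cells carry exact Clopper-Pearson 95% intervals, and a count of 0 allows up to 3 cells. Intervals and floors cover counting error only.

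Alternatives were DESeq2 1.42.0, library size alone, no filter on low windows, windows shifted by 40 kb, a minimum of 1000 cuts or none, plates as libraries, autosomes only, a replicate block by mark and none by cluster, all cuts for the clusters, the top 5% or 20% of windows, no thinning, a single ranking, Leiden resolutions of 1.0 and 0.25, 10 components, the window mean over all preparations, seed 2, and leaving out each preparation or replicate. Leaving out wells above 10 times the 95th percentile was added after the data were seen. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9 and R 4.3.3 were used.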

Results

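Single-cell chromatin immunocleavage sequencing (scChIC-seq) places an antibody and a protein A-MNase fusion on a histone modification inside single cells, so that each sequenced cut marks a nearby modified nucleosome. The series holds such cuts for mouse bone marrow and for K562, a human chronic myelogenous leukaemia line with erythroid features. The modifications were H3K4me1, which lies at enhancers and around promoters, H3K4me3, which lies at promoters, H3K27me3, the Polycomb mark, and H3K9me3, the mark of constitutive heterochromatin. Marrow cells came from 2 FVB preparations of 8 weeks, named m1 and m2, and 1 B6 preparation of 13 weeks, named m1. K562 cells came as replicates 1, 2 and 3. Of the 80 samples, 64 held marrow plates and 16 held K562 plates, several of them repeat runs of one plate.

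The tables held 16895 cells, of which 14429 had at least 500 cuts and were kept. Kept cuts, in units of 1e6 and in the order FVB m1, FVB m2 and B6 m1, were 3.46, 3.46 and 9.1 for H3K4me1 and 1.59, 1.37 and 4.57 for H3K4me3. They were 12.02, 11.16 and 22.12 for H3K27me3 and 5.35, 4.69 and 15.91 for H3K9me3. In K562 replicates 1, 2 and 3 they were 5.95, 3.93 and 0.24 for H3K4me1, 1.07, 0.66 and 0.91 for H3K4me3, 11.41, 15.96 and 4.66 for H3K27me3, and 12.66, 7.99 and 7.95 for H3K9me3. The median number of cuts per cell ranged over libraries from 970 to 24103. A single well held 12115910 cuts, 75.9% of K562 H3K27me3 replicate 2, and another held 191718 cuts, 9.9% of its B6 H3K4me1 plate.

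Bone marrow was first compared between marks, to ask which 100 kb windows carried each mark above the mean of the other 3. H3K4me1 was higher at marker genes of many blood lineages. Gfi1, a repressor that directs granulocyte differentiation (5:107716655 to 107725805), stood at 145 ± 33.1 CPM (SD, n = 3) against 65.3 ± 55.4 CPM in the libraries of the other marks (n = 9). This was a log2 fold of 1.64 ± 0.18 (SE, edgeR adjusted p = 4.37e-06). Ebf1, the early B cell factor (11:44618100 to 45008096), stood at 83.7 ± 11.5 CPM against 38 ± 19.2 CPM, a log2 fold of 1.35 ± 0.16 (edgeR adjusted p = 9.91e-06). Msi2, an RNA-binding protein of stem cells (11:88339382 to 88718306), reached 86.9 ± 15.9 CPM against 28.7 ± 20.2 CPM. Tfrc, the transferrin receptor of erythroid precursors (16:32608896 to 32632794), reached 126 ± 31.9 CPM against 68.2 ± 59.2 CPM. Among windows of at least 20 CPM, one holding Zmiz1 (14:25457875 to 25666743) had a log2 fold of 2.52 ± 0.30.

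All 9 lists of blood cell markers rose in H3K4me1 by camera with the preset correlation, and 0 of 18 lists passed with an estimated one. Lists were compared with all windows, of which 56.5% hold no protein-coding gene. Across windows the mean Spearman rho of a mark with gene density was 0.448 for H3K4me1, 0.503 for H3K4me3 and −0.443 for H3K9me3. A rise or fall against all windows need thus not be particular to blood cell genes. Windows were higher in 17 of 18 for granulocytes, 11 of 18 for erythroid cells, 17 of 18 for B cells, 13 of 19 for T and NK cells and 14 of 20 for monocytes and macrophages. They were higher in 15 of 19 for stem and progenitor cells, 8 of 10 for plasmacytoid dendritic cells, 8 of 9 for megakaryocytes and 8 of 9 for eosinophils, basophils and mast cells. None of these windows was lower, and adjusted over the list alone the erythroid count was 9 and the others were as given. In the same order the list medians relative to all windows were 1.20, 0.68, 1.30, 1.03, 1.21, 1.02, 1.19, 1.19 and 0.87 on the log2 scale, with camera adjusted p of 0.000206, 0.0158, 1.61e-06, 0.00221, 0.000206, 4e-05, 0.00221, 0.00142 and 0.00696. Each of these had an adjusted p of 0.449 with an estimated correlation. Housekeeping genes rose as well, with 22 of 24 windows higher (median 1.11, adjusted p = 1.07e-05, or adjusted p = 0.449 with an estimated correlation). Zinc finger genes had 134 windows higher and 60 lower of 298, or 134 and 56 adjusted over the list alone (median 0.49, adjusted p = 0.00255, or adjusted p = 0.625 with an estimated correlation).

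H3K4me1 was lower at the receptor families of sensory neurons. Olfactory receptor windows were lower in 223 of 344 and higher in 32, with the same counts adjusted over the list alone (median relative to all windows −0.59, adjusted p = 1.61e-06, or adjusted p = 0.449 with an estimated correlation). Vomeronasal receptor windows were lower in 144 of 181 and higher in 6, or 146 and 7 adjusted over the list alone (median −0.79, adjusted p = 5.74e-10, or adjusted p = 0.449 with an estimated correlation). Irx1, a patterning factor of the embryo (13:71958232 to 71963723), stood at 8.8 ± 1.37 CPM against 33.6 ± 28.5 CPM, and its log2 fold was −1.52 ± 0.22. The remaining lists did not pass. Developmental transcription factors had 15 of 45 windows lower and 2 higher (adjusted p = 0.0549), and neuronal and liver genes 8 of 20 lower and 4 higher (adjusted p = 0.18). Stroma, endothelium and bone genes had 6 of 15 higher and 1 lower (adjusted p = 0.266), and protocadherins 6 of 8 lower and 1 higher (adjusted p = 0.065). Their adjusted p with an estimated correlation were 0.713, 0.504, 0.713 and 0.449. At the Hox clusters 0 of 9 windows passed in edgeR, 0 also at an unadjusted p under 0.05 (camera adjusted p = 0.968, or adjusted p = 0.989 with an estimated correlation). Their list median of 0.24 had the opposite sign to the test.

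H3K4me3 was higher at genes that most cells use. All 24 housekeeping windows were higher (median relative to all windows 2.04, camera adjusted p = 6.31e-15, or adjusted p = 0.557 with an estimated correlation). The window of Gapdh, a glycolytic enzyme, held 140.1 ± 24.8 CPM (n = 3) with a log2 fold of 2.63 ± 0.18. Cd3d and Cd3g, chains of the T cell receptor complex (9:44969572 to 44987052), share a window with Atp5l and Ube4a. This window stood at 147 ± 6.61 CPM (n = 3) against 51.2 ± 39.2 CPM (n = 9), which cannot be assigned to 1 of these genes. Ngp, a neutrophil granule protein (9:110419808 to 110423012), stood at 143 ± 29.3 CPM against 49.9 ± 44.1 CPM. The steepest named windows held Aurkb, a mitotic kinase, at 303 ± 29.8 CPM against 78.3 ± 78.7 CPM. Zinc finger windows were higher in 216 of 298 and lower in 17, or 217 and 19 adjusted over the list alone (median 1.33, adjusted p = 3.79e-19, or adjusted p = 0.557 with an estimated correlation). The window shared by Zfp282 and Zfp398 (6:47835633 to 47908485) held 161 ± 20.1 CPM.

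The 9 blood cell lists also passed in H3K4me3. In the order used above, 18 of 18, 12 of 18, 17 of 18, 13 of 19, 11 of 20, 11 of 19, 8 of 10, 7 of 9 and 6 of 9 windows were higher. In addition 1 T and NK cell window and 1 stem and progenitor window were lower, and counts adjusted over the list alone were identical. Medians relative to all windows were 1.78, 1.51, 1.47, 1.18, 1.23, 1.01, 1.52, 1.26 and 1.24, with adjusted p of 3.6e-06, 0.00117, 2.34e-05, 0.000399, 0.00315, 0.00572, 0.000309, 0.0064 and 0.028. With an estimated correlation the adjusted p lay between 0.557 and 0.579. Developmental transcription factors fell, with 22 of 45 windows lower and 3 higher, or 21 and 3 adjusted over the list alone (median −0.25, adjusted p = 0.00572, or adjusted p = 0.677 with an estimated correlation). Vomeronasal windows were lower in 54 of 181 and higher in 13, or 20 and 10 adjusted over the list alone (median −0.15, adjusted p = 0.0054, or adjusted p = 0.677 with an estimated correlation). Olfactory windows were lower in 160 of 344 and higher in 55, or 157 and 54 adjusted over the list alone (median −0.20, adjusted p = 0.00572, or adjusted p = 0.611 with an estimated correlation). However, their mean lay above the median of all windows. Stroma, endothelium and bone (5 of 15 higher, 3 lower, adjusted p = 0.224), Hox (1 of 9 higher, adjusted p = 0.695), neuronal and liver genes (10 of 20 lower, 3 higher, adjusted p = 0.466) and protocadherins (6 of 8 lower, 1 higher, adjusted p = 0.22) did not pass. With an estimated correlation their adjusted p were 0.677, 0.89, 0.677 and 0.579, and the neuronal and liver median (−0.23) and mean had opposite signs relative to all windows.

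H3K27me3 was higher at regulators of other tissues. Msx1, a limb and craniofacial factor (5:37820491 to 37824585), stood at 46 ± 13.9 CPM (n = 3) against 14.8 ± 6.25 CPM (n = 9), a log2 fold of 1.72 ± 0.19 (edgeR adjusted p = 2.24e-05). Sox1, a neural factor (8:12395519 to 12399555), stood at 51.8 ± 20.6 CPM against 16.1 ± 3.73 CPM. Developmental transcription factor windows were higher in 38 of 45 and lower in none, or 39 adjusted over the list alone (median relative to all windows 1.09, camera adjusted p = 9.79e-10, or adjusted p = 0.958 with an estimated correlation). Stroma, endothelium and bone genes were higher in 10 of 15 windows and lower in 1 (median 0.79, adjusted p = 0.0163, or adjusted p = 0.958 with an estimated correlation). Among them Cxcl12, a niche chemokine (6:117168535 to 117181368), stood at 53.6 ± 21.1 CPM against 20.5 ± 2.68 CPM. Cdk6, a kinase of cycling progenitors (5:3341004 to 3531008), was lower, at 23.3 ± 1.47 CPM against 69.4 ± 45.3 CPM (log2 fold −1.19 ± 0.19). Vomeronasal windows were lower in 106 of 181 and higher in 3, or 107 and 3 adjusted over the list alone (median −0.68, adjusted p = 5.68e-09, or adjusted p = 0.958 with an estimated correlation). Zinc finger windows were lower in 106 of 298 and higher in 35, or 103 and 35 adjusted over the list alone (median −0.24, adjusted p = 0.0163, or adjusted p = 0.958 with an estimated correlation). Their median fold of −0.27 moved to 0.01 under scaling by library size.

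The other 14 lists did not pass in H3K27me3. Granulocyte windows were lower in 2 of 18, erythroid windows higher in 2 and lower in 2 of 18, B cell windows higher in 1 and lower in 1 of 18, and T and NK cell windows higher in 6 and lower in 1 of 19. Monocyte and macrophage windows were higher in 5 and lower in 4 of 20, and stem and progenitor windows higher in 6 and lower in 3 of 19. Their adjusted p were 0.756, 0.862, 0.862, 0.584, 0.81 and 0.862. Plasmacytoid dendritic cell genes (2 of 10 higher, adjusted p = 0.862) and megakaryocyte genes (1 higher and 1 lower of 9, adjusted p = 0.81) gave no call. Eosinophil, basophil and mast cell genes (2 higher and 3 lower of 9, adjusted p = 0.81) and Hox clusters (3 of 9 higher, adjusted p = 0.715) gave no call either. The same held for housekeeping genes (2 higher and 7 lower of 24, adjusted p = 0.715), and neuronal and liver genes (8 higher and 3 lower of 20, adjusted p = 0.458). Nor did olfactory receptors (62 higher and 115 lower of 344, adjusted p = 0.256) or protocadherins (1 of 8 higher, adjusted p = 0.756) pass. With an estimated correlation each had an adjusted p of 0.958. The erythroid median of 0.06 and the B cell mean log2 fold of 0.01 had the opposite sign to their tests.

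H3K9me3 fell at housekeeping genes and rose at receptor families. Polr2a, the largest subunit of RNA polymerase II (11:69733997 to 69758633), stood at 8.84 ± 0.918 CPM (n = 3) against 101 ± 45.8 CPM (n = 9), a log2 fold of −3.39 ± 0.26 (edgeR adjusted p = 7.96e-09). Csmd1, a neuronal gene of over a megabase (8:15892538 to 17535385), stood at 89.2 ± 30 CPM against 11.6 ± 2.5 CPM, a log2 fold of 2.94 ± 0.20 (edgeR adjusted p = 4.17e-09). Vmn1r70, a vomeronasal receptor (7:10633587 to 10634483), stood at 117 ± 38.7 CPM against 15.3 ± 4.12 CPM. Vomeronasal windows were higher in 156 of 181 and lower in 11 (median relative to all windows 2.38, camera adjusted p = 1.36e-10). Olfactory windows were higher in 219 of 344 and lower in 84, or 83 adjusted over the list alone (median 1.56, adjusted p = 4.45e-05). Housekeeping windows were lower in 24 of 24 (median −2.55, adjusted p = 1.04e-06), and zinc finger windows lower in 208 of 298 and higher in 60 (median −1.17, adjusted p = 3.06e-06). Each of these had an adjusted p of 0.468 with an estimated correlation.

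The blood cell lists fell in H3K9me3 in the order 18 of 18, 14 of 18, 18 of 18, 17 of 19, 19 of 20, 17 of 19, 10 of 10, 9 of 9 and 7 of 9 windows lower, with 1 erythroid and 1 T and NK cell window higher. Medians were −2.37, −1.41, −2.08, −1.82, −1.63, −1.63, −2.29, −2.43 and −1.43, and adjusted p were 0.000378, 0.00378, 4.16e-05, 0.000378, 0.000516, 0.00061, 0.00125, 0.00326 and 0.0244, each with an adjusted p of 0.468 with an estimated correlation. Stroma, endothelium and bone windows were lower in 11 of 15 and higher in 1 (median −1.24, adjusted p = 0.0292, or adjusted p = 0.539 with an estimated correlation). Counts adjusted over the list alone were identical for these lists. Hox clusters (4 of 9 lower, 3 adjusted over the list alone, adjusted p = 0.388) and developmental factors (10 higher and 15 lower of 45, adjusted p = 0.69) did not pass. Neither did neuronal and liver genes (10 higher and 9 lower of 20, adjusted p = 0.69) or protocadherins (6 higher and 1 lower of 8, adjusted p = 0.284). With an estimated correlation their adjusted p were 0.835, 0.929, 0.88 and 0.559.

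**Figure D1:**
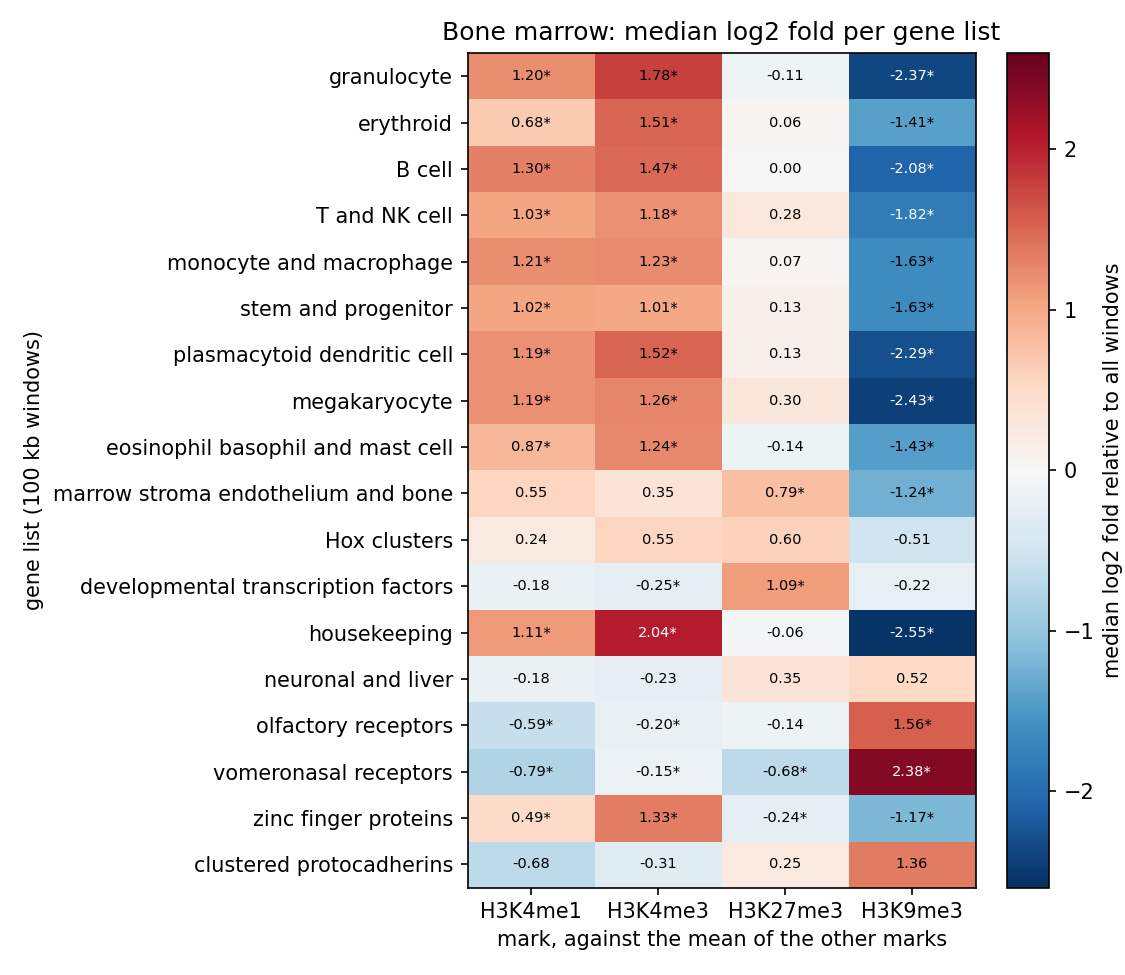
Median log2 fold of each gene list (18 on the vertical axis) in each mark (4 on the horizontal axis) of bone marrow, relative to the median of all windows and so unmoved by the scaling, with the colour scale in log2 units and a star where the list passed camera with the preset correlation. The 24 housekeeping windows lay at 1.11, 2.04, −0.06 and −2.55 for H3K4me1, H3K4me3, H3K27me3 and H3K9me3, vomeronasal receptors lay highest in H3K9me3 at 2.38, and the absolute zinc finger median in H3K27me3 turned from −0.27 to 0.01 under scaling by library size.

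Over all 25705 windows tested in marrow, edgeR called 18957 for H3K4me1 (8475 higher, 10482 lower), 17636 for H3K4me3 (7490 higher, 10146 lower), 13606 for H3K27me3 (6749 higher, 6857 lower) and 23347 for H3K9me3 (11372 higher, 11975 lower). With library size alone the median of all windows moved by 0.28 for H3K27me3 and −0.17 for H3K9me3, and the H3K27me3 split became 9832 higher and 3499 lower. Without FVB m1 the counts were 12306 for H3K4me1, 8473 for H3K4me3 and 8564 for H3K27me3, and without FVB m2 the H3K4me3 count was 11395. At genes named for every mark, S100a8, an alarmin of granulocytes (3:90669071 to 90670034), had log2 folds of 0.98 ± 0.30 in H3K4me1, 1.66 ± 0.29 in H3K4me3 and −2.52 ± 0.37 in H3K9me3. In H3K27me3 its −0.12 ± 0.31 did not pass (edgeR adjusted p = 0.765). Hbb-bs, an adult beta globin (7:103826523 to 103827928), passed at 0.50 ± 0.18 in H3K4me1 and −0.70 ± 0.19 in H3K9me3, and stood at 0.23 ± 0.19 in H3K4me3 without passing. Sox6, a repressor of embryonic globin (7:115470872 to 116040776), passed at 0.57 ± 0.16 in H3K4me1, 0.54 ± 0.16 in H3K27me3 and −1.27 ± 0.18 in H3K9me3. Ebf1 passed at 0.51 ± 0.18 in H3K4me3 and −2.04 ± 0.20 in H3K9me3, and Gapdh (6:125161852 to 125166467) at 1.73 ± 0.18 in H3K4me1, −0.97 ± 0.21 in H3K27me3 and −3.38 ± 0.25 in H3K9me3. No mark passed at Hoxa9 or Hoxd9, and at Hoxa9 the edgeR adjusted p were 0.203, 0.179, 0.428 and 0.0843 for H3K4me1, H3K4me3, H3K27me3 and H3K9me3.

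K562 was compared in the same way, with windows given by the coordinates of the tables, whose human build is not given in the sources used here. Among called windows with a mean of at least 20 CPM, H3K4me3 had its largest fold at 6:31800001 to 31900000, with 1179 ± 317 CPM (n = 3) against 69.5 ± 84.5 CPM (n = 9), a log2 fold of 5.21 ± 0.21 (edgeR adjusted p = 2.89e-10). A window at 19:1200001 to 1300000 stood 4.99 ± 0.20 higher in H3K4me3 and −3.80 ± 0.28 in H3K9me3. H3K4me1 reached 116 ± 14.9 CPM against 12.9 ± 11.3 CPM at 10:79100001 to 79200000 and 171 ± 17.1 CPM against 27 ± 28.4 CPM at 8:127900001 to 128000000. H3K9me3 stood at 87.5 ± 23.5 CPM against 4.27 ± 5.68 CPM at 18:64200001 to 64300000, where H3K4me3 held 0.354 ± 0.613 CPM. Among such windows H3K27me3 had its lowest folds at 6:26200001 to 26300000, with 11.5 ± 4.62 CPM against 339.8 ± 379 CPM (log2 fold −3.96 ± 0.31), and at 6:27800001 to 27900000, with 10.2 ± 3.36 CPM against 351 ± 423 CPM (log2 fold −3.92 ± 0.29). Of 28628 windows, edgeR called 17679 for H3K4me1 (6920 higher, 10759 lower), 15592 for H3K4me3 (6435 and 9157), 17017 for H3K27me3 (8697 and 8320) and 19282 for H3K9me3 (11638 and 7644). Under library size alone the splits were 8584 and 8042 for H3K4me1, 11364 and 4408 for H3K27me3 and 9857 and 13253 for H3K9me3, and the medians moved by 0.31, −0.16, 0.73 and −0.75. Without replicate 1 or replicate 3 the H3K4me3 count was 8010 or 7932.

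The pairs of marks were then compared across windows within each preparation, as Spearman coefficients that describe windows and carry no p. H3K4me1 and H3K4me3 ran together in marrow (rho 0.937 ± 0.0148, SD, n = 3) and in K562 (0.803 ± 0.0343, n = 3). H3K4me1 and H3K27me3 correlated at 0.689 ± 0.0782 in marrow and 0.347 ± 0.164 in K562, and H3K4me3 and H3K27me3 at 0.656 ± 0.0826 and 0.153 ± 0.133. H3K9me3 ran against H3K4me1 at −0.475 ± 0.0904 in marrow and −0.392 ± 0.00681 in K562, against H3K4me3 at −0.433 ± 0.0831 and −0.195 ± 0.0153, and against H3K27me3 at −0.316 ± 0.192 and −0.236 ± 0.223. The last pair of values depended on single replicates: without B6 m1 the marrow value was −0.206, and in K562 it was −0.142 without replicate 1 and −0.359 without replicate 2, which had 75.9% of its H3K27me3 cuts in 1 well. Without replicate 2 H3K4me3 and H3K27me3 correlated at 0.23 in K562. Leaving out replicates was chosen here after seeing the data. Between preparations of marrow one mark correlated with itself at 0.892 to 0.962 on average. Windows without a protein-coding gene were 56.5% of all and held 40.2 ± 2.84% of H3K4me1 cuts, 35.7 ± 1.74% of H3K4me3, 49.7 ± 4.39% of H3K27me3 and 72.9 ± 2.38% of H3K9me3 cuts (SD, n = 3).

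The title of the series speaks of focusing of chromatin domains, so the share of cuts in the 10% of windows with most cuts was measured for each library. In marrow this share was 27.4 ± 3.71% for H3K4me1, 31.2 ± 2.43% for H3K4me3, 17.5 ± 4.39% for H3K27me3 and 26.3 ± 4.12% for H3K9me3 (SD, n = 3). H3K27me3 lay below every other mark in 9 of 9 pairs of libraries, by 9.94 points against H3K4me1 and 13.7 points against H3K4me3 (two-sided exact permutation p = 0.1 each, adjusted over 6 pairs p = 0.2). In K562 the shares were 33.2 ± 3.01%, 47.6 ± 3.63%, 22.9 ± 8.94% and 29.9 ± 2.9%. H3K4me3 lay above H3K27me3 by 24.7 points and above H3K9me3 by 17.7 points in 9 of 9 pairs (two-sided exact permutation p = 0.1 each, adjusted p = 0.2). A p of 0.1 is the smallest that 3 libraries against 3 can give, so no pair could pass 0.05. Within the marrow preparations H3K4me3 lay above H3K4me1 in 3 of 3 (30.5% against 25.8%, 29.1% against 24.9% and 33.8% against 31.7%). H3K4me1 lay above H3K9me3 in 3 of 3 as well (24.7%, 23.1% and 30.9%), and 3 pairs cannot give an exact p under 0.25. K562 H3K27me3 rested on 1 well: without the wells above 10 times the 95th percentile, an alternative chosen after seeing the data, replicate 2 moved from 12.9% to 29.1% and the mean to 28.3 ± 2.24%.

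**Figure D2:**
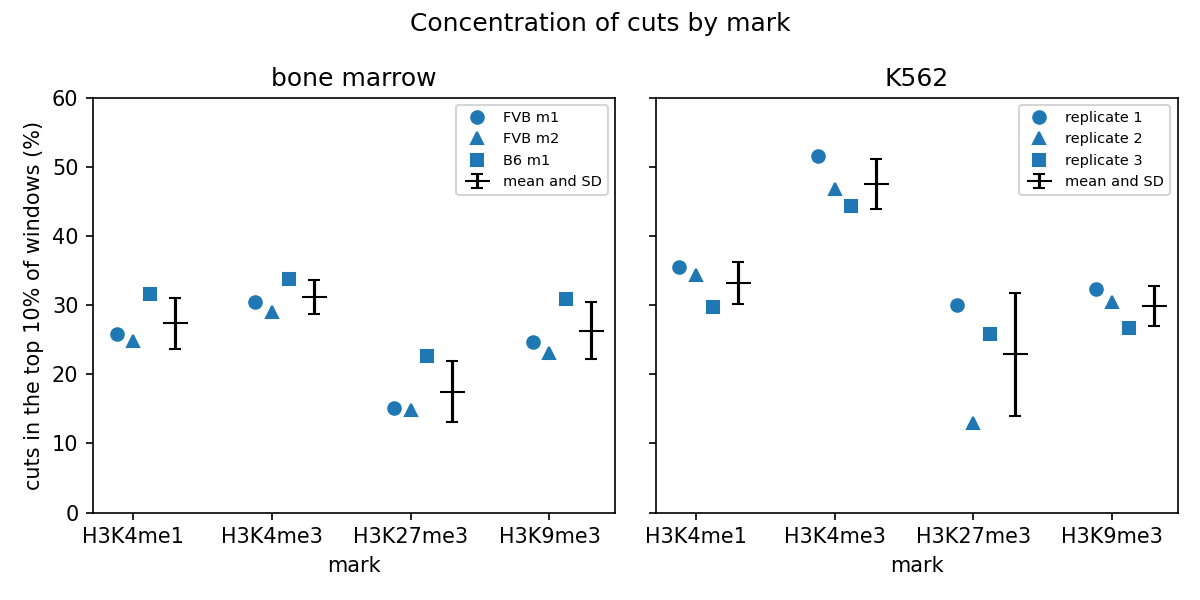
Share of cuts (percent, vertical axis from 0) in the 10% of windows with most cuts, for the 4 marks in bone marrow and in K562, with 1 point per preparation or replicate and the mean ± SD beside them. Marrow H3K27me3 sits lowest at 17.5 ± 4.39% and K562 H3K4me3 highest at 47.6 ± 3.63%, and the K562 H3K27me3 point at 12.9% is the library with 75.9% of its cuts in 1 well.

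Marrow cells were next grouped within each mark, to ask which cell types carried which windows. A random part of each cell's cuts formed the clusters and the rest of its cuts tested them, summed over the cells of a cluster and over all other cells of the same preparation. Clustering took 2708 cells for H3K4me1, 2429 for H3K4me3, 2778 for H3K27me3 and 2767 for H3K9me3 and gave 9, 5, 6 and 6 clusters. From marker lists, H3K4me1 clusters 1 and 6 were named B cell-like, 2 granulocyte-like, 5 erythroid-like, 7 monocyte and macrophage-like and 8 T and NK cell-like. H3K4me3 clusters 1 to 4 were named B cell-like, granulocyte-like, monocyte and macrophage-like and erythroid-like. A name needed a list median of 0.5 that led the next list by 0.2, limits set after these medians were seen, and H3K4me1 cluster 8 at 0.51 and H3K4me3 cluster 3 at 0.52 lay near them. H3K27me3 and H3K9me3 clusters kept numbers.

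The B cell-like clusters together held 30.9%, 22.5% and 25.1% of H3K4me1 cells in FVB m1, FVB m2 and B6 m1, and 47.4%, 49.9% and 38.9% of H3K4me3 cells. Granulocyte-like cells were 7.28%, 14.4% and 22.3% for H3K4me1, with exact 95% binomial intervals of 5.38 to 9.59, 11.8 to 17.4 and 20.2 to 24.6, and 35.9%, 33.8% and 38.5% for H3K4me3. Erythroid-like cells were 16.9%, 14% and 7.79% for H3K4me1 and 9.95%, 11.1% and 7.41% for H3K4me3. Monocyte and macrophage-like cells were 5.54%, 4.75% and 9.34% for H3K4me1 and 6.75%, 5.18% and 13.3% for H3K4me3, and T and NK cell-like cells 6.96%, 5.98% and 6.81% for H3K4me1. The limits kept out H3K4me1 clusters 3 (23.1%, 23.2% and 10.9%), 4 (9.34%, 15.2% and 14.4%, leading with granulocyte markers at a median of 0.31) and 9. Cluster 9 held 3.37% of B6 cells and 0 of 632 and 0 of 652 FVB cells, allowing up to 0.475% and 0.46%. H3K4me3 cluster 5 held 1.85% of B6 cells and 0 of 593 and 0 of 541 FVB cells, allowing up to 0.506% and 0.555%. H3K27me3 cluster 3 held 37.8% of B6 cells against 1.03% and 0.294% of FVB cells. H3K9me3 cluster 4 held 32.3% against 0.742% and 0.149%, and H3K9me3 cluster 6 held 6.38% and 6.84% of FVB cells and 0 of 1420 B6 cells, allowing up to 0.211%. Clusters with under 20 cells in a preparation were not tested, and shares were not tested between preparations.

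The H3K4me1 clusters were then compared at single windows. In B cell-like cluster 1, Pax5, the B cell commitment factor (4:44524748 to 44710694), stood at 179.9 ± 46 CPM (SD, n = 3) against 52.9 ± 9.15 CPM in the other cells (n = 3), a log2 fold of 1.80 ± 0.18 (SE, edgeR adjusted p = 4.5e-20). Rag1 and Rag2, the recombinase of antigen receptor genes (window 2:101600001 to 101700000), stood at 221 ± 40.3 CPM against 75.1 ± 9.68 CPM. Granulocyte-like cluster 2 carried 279 ± 92.1 CPM against 77.9 ± 33.8 CPM at S100a8 and S100a9 (log2 fold 1.79 ± 0.13). It carried 12.5 ± 3.19 CPM against 77.8 ± 15.1 CPM at Pax5 (log2 fold −2.91 ± 0.32). Erythroid-like cluster 5 carried 147 ± 12.8 CPM against 23.6 ± 4.38 CPM at Ank1, which anchors the red cell membrane skeleton (8:22974836 to 23150501). It also carried 173 ± 37.8 CPM against 40.2 ± 9.01 CPM at Sox6. In B cell-like cluster 6 Bach2, a repressor of plasma cell fate (4:32238413 to 32586109), stood at 264 ± 79.1 CPM against 69.8 ± 2.26 CPM. Monocyte and macrophage-like cluster 7 held 109.9 ± 45.8 CPM against 33.3 ± 0.854 CPM at Fn1, fibronectin (1:71585473 to 71653280), and 19.5 ± 6.91 CPM against 84.9 ± 13.4 CPM at Ebf1. T and NK cell-like cluster 8 held 94.4 ± 29.1 CPM against 12.5 ± 0.881 CPM at Bcl11b, a T cell commitment factor (12:107910403 to 108004145). Eomes, a T-box factor of NK cells (9:118478186 to 118486132), stood there at 83.9 ± 36 CPM against 32.8 ± 4.81 CPM.

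Each named cluster also had its own marker list higher on the held-out cuts. Windows were higher in 17 of 18 for B cells in cluster 1 (18 adjusted over the list alone), 18 of 18 for granulocytes in cluster 2 and 14 of 18 for erythroid cells in cluster 5 (16). They were higher in 12 of 18 for B cells in cluster 6 (16), 8 of 20 for monocytes and macrophages in cluster 7 (14) and 7 of 19 for T and NK cells in cluster 8 (12). None of these windows was lower. Medians relative to all windows were 1.10, 1.39, 1.30, 0.88, 0.80 and 0.60, with camera adjusted p of 3.02e-21, 3.04e-16, 2.98e-25, 1.03e-20, 3.62e-15 and 3.55e-17. With an estimated correlation they had adjusted p = 0.412, 0.449, 0.487, 0.397, 0.706 and 0.41. The lists also served to name the clusters, so these calls are not independent of the names. Stem and progenitor windows were higher in 9 of 19 and lower in 1 in granulocyte-like cluster 2 (median 0.64, adjusted p = 0.00661, or adjusted p = 0.471 with an estimated correlation). In erythroid-like cluster 5 B cell windows were lower in 12 of 18 (13 adjusted over the list alone; median −1.26, adjusted p = 2.62e-10, or adjusted p = 0.487 with an estimated correlation). Monocyte and macrophage windows were lower in 11 of 20 (median −1.03, adjusted p = 5.18e-05, or adjusted p = 0.606 with an estimated correlation). Unnamed cluster 3 had 16 of 18 granulocyte windows lower (17 adjusted over the list alone; median −0.93, adjusted p = 5.52e-12, or adjusted p = 0.446 with an estimated correlation). It had 12 of 24 housekeeping windows lower (15 adjusted over the list alone; median −0.66, adjusted p = 1.72e-07, or adjusted p = 0.442 with an estimated correlation), and all 9 blood cell lists fell there with the preset correlation, while 0 of 18 lists passed with an estimated one (lowest adjusted p = 0.442). Unnamed cluster 4 had 3 of 18 granulocyte windows higher (median 0.25, adjusted p = 0.000581, or adjusted p = 0.612 with an estimated correlation). It had 5 of 18 B cell windows lower (11 adjusted over the list alone; median −0.49, adjusted p = 7.36e-08, or adjusted p = 0.612 with an estimated correlation).

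Over all windows edgeR called, for H3K4me1 clusters 1 to 8, 3883 (3006 higher, 877 lower), 5431 (3560, 1871), 5333 (1873, 3460), 1394 (735, 659), 5198 (1902, 3296), 2207 (1655, 552), 1024 (825, 199) and 414 (289, 125). Library size moved the median of all windows by −0.21, −0.19, 0.20, −0.17 and −0.14 in clusters 1, 2, 3, 6 and 7. The splits became 1919 and 1991, 2490 and 3567, 3142 and 2262, 999 and 923, and 661 and 398. DESeq2 called 1691, 2650, 1881, 135, 1993, 647, 143 and 40. Single preparations mattered for the counts: without B6 m1 they were 1745, 1964, 2056, 437, 2966, 477, 57 and 0, the last with 1899 windows at an unadjusted p under 0.05 in edgeR. Without FVB m1 clusters 4, 6 and 7 gave 828, 1221 and 527, and without FVB m2 clusters 3 and 4 gave 2539 and 736.

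H3K4me3 clusters carried the same lineage names, apart from T and NK cells, for which no cluster was named. Erythroid-like cluster 4 held 255 ± 50.8 CPM (n = 3) against 23.2 ± 9.48 CPM (n = 3) at Hbb-bs and Hbb-bt, the adult beta globins (window 7:103800001 to 103900000), a log2 fold of 3.34 ± 0.33 (edgeR adjusted p = 2.02e-07). Aqp1, the red cell water channel (6:55336299 to 55348555), stood there at 199 ± 16.4 CPM against 19.3 ± 5.42 CPM. Granulocyte-like cluster 2 held 343 ± 63.6 CPM against 79.3 ± 22.6 CPM at S100a8 and S100a9 and 199 ± 6.49 CPM against 52.2 ± 12.5 CPM at Cxcr2, a neutrophil chemokine receptor (1:74153994 to 74161246). B cell-like cluster 1 held 113 ± 36.3 CPM against 24.2 ± 10.9 CPM at Pax5, and monocyte and macrophage-like cluster 3 held 245 ± 27.4 CPM against 109 ± 9.45 CPM at Ms4a6c (19:11469353 to 11487182). Windows of the naming lists were higher in 12 of 17 for B cells (14 adjusted over the list alone), 16 of 18 for granulocytes (18), 3 of 19 for monocytes and macrophages (8) and 14 of 18 for erythroid cells (14) in clusters 1 to 4. Their medians were 0.82, 1.17, 0.49 and 1.58 relative to all windows, with camera adjusted p of 1.53e-11, 4.39e-29, 9.92e-09 and 2.6e-24 and adjusted p = 0.489, 0.358, 0.749 and 0.42 with an estimated correlation. Granulocyte windows were lower in 17 of 18 in cluster 1 (median −0.88, adjusted p = 2.61e-18, or adjusted p = 0.489 with an estimated correlation). B cell windows were lower in 7 and higher in 1 of 18 in cluster 2 (9 and 2 adjusted over the list alone; median −0.40, adjusted p = 0.000112, or adjusted p = 0.358 with an estimated correlation). EdgeR called 2258 windows (1147 higher, 1111 lower), 2577 (1566, 1011; 1280 and 1301 under library size), 84 (55, 29) and 1492 (739, 753) in clusters 1 to 4. DESeq2 called 223, 578, 3 and 171. Without B6 m1 the counts were 720, 781, 0 (800 at an unadjusted p under 0.05) and 3. Without FVB m1 they were 1703, 45 and 721 in clusters 2, 3 and 4, and without FVB m2 cluster 3 gave 39.

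**Figure D3:**
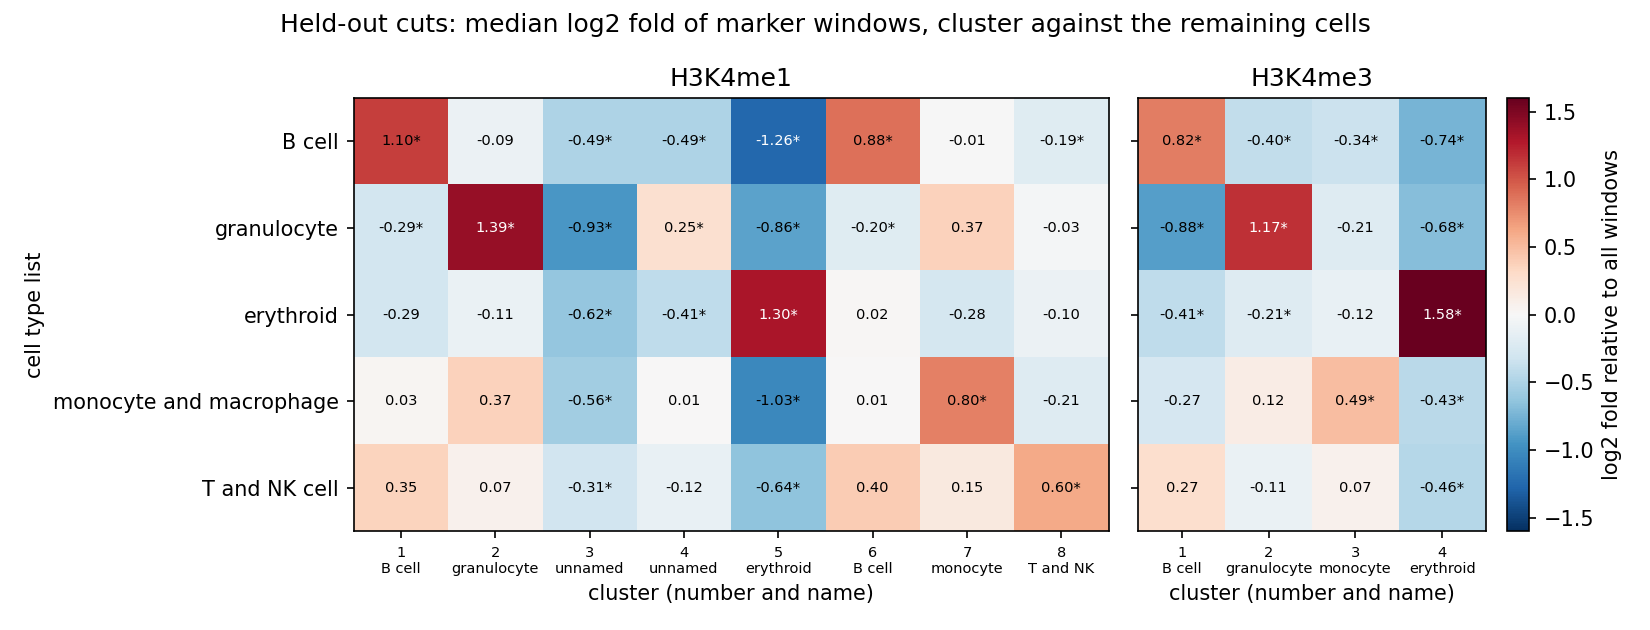
Median log2 fold of 5 cell type lists (rows) in each tested cluster of H3K4me1 (1 to 8) and H3K4me3 (1 to 4), cluster against the other cells of the same preparation on held-out cuts, relative to the median of all windows, with the colour scale in log2 units. The erythroid list reached 1.30 in H3K4me1 cluster 5 and 1.58 in H3K4me3 cluster 4, and the B cell list reached −1.26 in H3K4me1 cluster 5.

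H3K27me3 clusters differed at Hox genes, the body axis factors, and at other developmental transcription factors, among other windows. The share of cuts in the top 10% of windows moved the same way. Against the other cells it differed by −1.55 and −3.46 points in clusters 1 and 5, where Hox windows were lower. It differed by 2.75, 4.15 and 11.3 points in clusters 2, 4 and 6, where they were higher. Whether background cuts differ between these clusters was not tested. Hoxc10, Hoxc11 and Hoxc12, which share a window with further Hoxc genes (15:102900001 to 103000000), stood at 24.7 ± 18.2 CPM (n = 3) against 66.3 ± 37.1 CPM (n = 3) in cluster 1, a log2 fold of −1.44 ± 0.13 (edgeR adjusted p = 2.64e-09). They stood at 440.2 ± 51.6 CPM against 53.6 ± 35.8 CPM in cluster 6, a log2 fold of 3.06 ± 0.30 (edgeR adjusted p = 8.61e-20). Hoxd1, Hoxd3 and Hoxd4 (window 2:74700001 to 74800000) stood at 16.8 ± 12.5 CPM against 79.7 ± 57.4 CPM in cluster 5. Hox windows were lower in 9 of 9 in clusters 1 and 5 (medians −1.07 and −1.74 relative to all windows), higher in 9 of 9 in clusters 2 and 4 (0.72 and 0.81) and higher in 7 of 9 in cluster 6 (8 adjusted over the list alone; 1.71). In the order 1, 2, 4, 5 and 6 the camera adjusted p were 3.88e-36, 2.33e-08, 6.72e-08, 2.4e-17 and 1.09e-15, and adjusted p = 0.268, 0.296, 0.38, 0.492 and 0.193 with an estimated correlation. Developmental factor windows were lower in 37 of 45 in cluster 1 (39 adjusted over the list alone), higher in 33 in cluster 2 and 41 in cluster 4 (42), lower in 39 in cluster 5 (40), and higher in 10 and lower in 1 in cluster 6 (20 and 1). Camera adjusted p were 5.73e-34, 7.21e-13, 1.69e-18, 4.51e-27 and 8.34e-12, with adjusted p = 0.268, 0.215, 0.38, 0.492 and 0.193 with an estimated correlation. Cluster 6 held shallow cells: its developmental factor windows stood 1.05 above the median window against all other cells, and 0.19 (0.09, 0.67 and −0.18 by preparation) against the 738 cells of similar depth.

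In the H3K27me3 clusters many lists moved one way with the preset correlation, with 13 and 14 of the 18 lists lower in clusters 1 and 5, and 9, 7 and 10 higher in clusters 2, 4 and 6, while 0 of 18 passed in any of them with an estimated correlation. The rises of B cell genes in cluster 4 and of erythroid genes in cluster 6 were thus among several. Pax5 stood at 25.6 ± 12.5 CPM against 56.8 ± 15.6 CPM in cluster 2 (log2 fold −1.13 ± 0.16). It stood at 91.7 ± 22.2 CPM against 42.1 ± 17.8 CPM in cluster 4 (log2 fold 1.16 ± 0.17), where Blk, a B cell kinase (14:63372837 to 63417187), stood at 92.2 ± 9.78 CPM against 48.3 ± 25.8 CPM. B cell windows were higher in 8 of 18 in cluster 4 (median 0.39, adjusted p = 0.000272, or adjusted p = 0.38 with an estimated correlation). Vomeronasal windows were lower in 79 of 170 there and higher in 4, or 87 and 5 adjusted over the list alone (median −0.61, adjusted p = 1.97e-09, or adjusted p = 0.38 with an estimated correlation). They were higher in 71 and lower in 22 of 173 in cluster 5 (83 and 22 adjusted over the list alone; median 0.49, adjusted p = 6.36e-05, or adjusted p = 0.492 with an estimated correlation). Cluster 6, whose cells had a median of 2135 cuts against 10874 for all cells, held 215 ± 41.8 CPM against 45 ± 3.38 CPM at Hbb-bs and Hbb-bt. Its erythroid windows were higher in 6 of 18 (11 adjusted over the list alone; median 1.34, adjusted p = 1.79e-11, or adjusted p = 0.195 with an estimated correlation). Counts were 3839 (875 higher, 2964 lower) in cluster 1, 9139 (4761, 4378) in 2, 8997 (4690, 4307) in 4, 10288 (4894, 5394) in 5 and 884 (602, 282) in 6. DESeq2 called 1853, 2681, 3249, 5396 and 458. Under library size the splits of the first 4 were 1438 and 1968, 3055 and 5824, 2731 and 6361, and 6654 and 3273, with median shifts of −0.13 and 0.13 in clusters 4 and 5. Without FVB m1 the counts were 1730, 4831, 414, 3876 and 345. Without FVB m2 clusters 2, 4, 5 and 6 gave 3771, 1823, 3018 and 295, and without B6 m1 clusters 1 and 6 gave 2225 and 0 (809 at an unadjusted p under 0.05).

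H3K9me3 clusters differed at receptor families, among other lists. In cluster 5 the window of Vmn1r170, Vmn1r171 and Vmn1r172 (7:23600001 to 23700000) stood at 176 ± 33.5 CPM (n = 3) against 90.9 ± 25.9 CPM (n = 3), a log2 fold of 0.96 ± 0.18 (edgeR adjusted p = 0.000266). Vomeronasal windows were higher in 86 of 178 and lower in 5, or 94 and 6 adjusted over the list alone (median relative to all windows 0.80, camera adjusted p = 1.4e-12, or adjusted p = 0.27 with an estimated correlation). Olfactory windows were higher in 100 and lower in 23 of 341 there (105 and 27 adjusted over the list alone; median 0.53, adjusted p = 0.00256, or adjusted p = 0.27 with an estimated correlation). Their mean fold before centring was −0.04. Cluster 1 ran the other way, with vomeronasal windows lower in 128 and higher in 7 of 178 (129 and 7 adjusted over the list alone; median −0.77, adjusted p = 1.29e-14, or adjusted p = 0.356 with an estimated correlation). Olfactory windows were lower there in 169 and higher in 73 of 344 (median −0.49, adjusted p = 0.00139, or adjusted p = 0.356 with an estimated correlation). There 12 of the 18 lists rose and 2 fell with the preset correlation (0 of 18 passed with an estimated one), so the rises given next were among several. Housekeeping windows were higher in 13 of 21 (median 0.46, adjusted p = 0.00139, or adjusted p = 0.356 with an estimated correlation). Rag1 and Rag2 stood at 27.3 ± 3.45 CPM against 12.3 ± 3.9 CPM. B cell windows were higher in 13 of 16 (median 0.57, adjusted p = 0.00139, or adjusted p = 0.356 with an estimated correlation) and monocyte and macrophage windows in 16 of 20 (median 0.45, adjusted p = 0.00107, or adjusted p = 0.356 with an estimated correlation). Vomeronasal windows were also higher in 37 and lower in 2 of 179 in cluster 2 (45 and 2 adjusted over the list alone; median 0.22, adjusted p = 1.99e-09, or adjusted p = 0.303 with an estimated correlation). In cluster 3 they were higher in 6 and lower in 1 of 178, or 5 and 1 adjusted over the list alone (median 0.21, adjusted p = 3.28e-06, or adjusted p = 0.635 with an estimated correlation). Clusters 1, 2, 3 and 5 had 15774 windows called (8068 higher, 7706 lower), 3605 (2260, 1345), 1476 (1022, 454) and 6675 (4148, 2527). DESeq2 called 7025, 557, 42 and 3755. Under library size, which moved the medians by 0.25, −0.10, −0.15 and −0.21, the splits were 12475 and 4245, 623 and 1849, 455 and 1118, and 2057 and 4557. Without FVB m1 the counts were 9858, 1387, 449 and 1343, without FVB m2 clusters 2, 3 and 5 gave 2171, 813 and 1309, and without B6 m1 clusters 2 and 3 gave 472 and 24.

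The share of cuts in the 10% of windows with most cuts was then compared between each cluster and the other cells of the same preparation, on sums thinned to equal cuts. Granulocyte-like cells of H3K4me1 held 34.3% against 24.2%, a difference of 10.1 ± 1.29 points (SD, n = 3), and the B cell-like clusters 1 and 6 held 6.26 ± 1.04 and 6.34 ± 2.17 points more. Cluster 3 of H3K4me1 lay lower by a difference of −7.39 ± 3.28 points, and erythroid-like cluster 5 differed by 2.54 ± 4.44 points, less than its spread. Monocyte and macrophage-like cluster 7 and T and NK cell-like cluster 8 held 3.47 ± 3.02 and 1.65 ± 1.26 points more, and cluster 4 differed by −0.212 ± 1.33 points, which became 0.372 without B6 m1 and 0.373 with the top 20% of windows. With windows ranked once per preparation clusters 1, 2, 5 and 6 differed by 2.81, 6.69, −3.04 and 3.59 points, and without thinning cluster 8 differed by 0.141. For H3K4me3 the differences were −2.35 ± 0.734, 3.79 ± 0.834, 0.148 ± 1.46 and 2.62 ± 1.62 points in B cell-like, granulocyte-like, monocyte and macrophage-like and erythroid-like cells, and the third became −0.696 without B6 m1. The last pair depended on the measure: with windows ranked once per preparation they were −0.866 and −1.19 points, and without thinning −2.34 and 0.343 points. H3K27me3 gave −1.55 ± 1.3, 2.75 ± 0.278, 4.15 ± 0.498, −3.46 ± 2.5 and 11.3 ± 2.71 points in clusters 1, 2, 4, 5 and 6, of which the last pair became −6.55 and 1.91 with windows ranked once. H3K9me3 gave −7.61 ± 1.41, 2.48 ± 1.74, 3.61 ± 0.652 and 9.72 ± 2.36 points in clusters 1, 2, 3 and 5. Clusters whose 3 preparations moved one way had a two-sided exact sign-flip permutation p of 0.25, the smallest that 3 pairs can give, so none could pass 0.05.

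The B6 preparation was compared with the FVB preparations within each mark. Strain, age, sequencing run and the deposited tables change together here, so the comparison is between these preparations. Among the widest differences were a few windows higher in B6. At 2:98600001 to 98700000, which holds the midpoint of no protein-coding gene, B6 had 4913 CPM (n = 1) against 18.4 ± 1.54 CPM (SD, n = 2) in H3K4me1, a log2 fold of 8.06 ± 0.26 (SE). It had 24152 CPM against 83.7 ± 9.53 CPM in H3K9me3. These CPM are scaled by the TMM factors, and from the raw counts the H3K9me3 values were 17023 CPM and 86 CPM. At 14:19400001 to 19500000 it had 593 CPM against 3.73 ± 0.541 CPM in H3K4me1 and 8048 CPM against 17.6 ± 3.98 CPM in H3K9me3 (5673 CPM and 18 CPM from the raw counts). Chl1, a neural adhesion gene (6:103510584 to 103733038), had 4942 CPM against 37.8 ± 0.3 CPM in H3K9me3 (3483 CPM and 39 CPM from the raw counts). Lower in B6 were Vmn1r114, Vmn1r115 and Vmn1r116, vomeronasal receptors (window 7:20800001 to 20900000), at 2.18 CPM against 16 ± 0.98 CPM in H3K4me1 (log2 fold −2.87 ± 0.31). Mup16 and Mup17, major urinary proteins (window 4:61500001 to 61600000), stood at 4.62 CPM against 22.6 ± 0.291 CPM in H3K27me3.

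Among blood cell genes, Padi4, a neutrophil histone deiminase (4:140745508 to 140774239), stood at 98.8 CPM (n = 1) against 32.7 ± 1.37 CPM (n = 2) in B6 H3K4me1, a log2 fold of 1.59 ± 0.13. S100a8 and S100a9 stood at 173 CPM against 74.6 ± 7.7 CPM. Granulocyte-like cells made up 22.3% of B6 H3K4me1 cells against 7.28% and 14.4%, and 38.5% of B6 H3K4me3 cells against 35.9% and 33.8%. In H3K27me3 Hoxc4, Hoxc5 and Hoxc6 (window 15:103000001 to 103100000) stood at 117 CPM against 27.9 ± 2.99 CPM (log2 fold 2.06 ± 0.10). B6 was 1 preparation, so its own spread is unmeasured. The calls take the spread from the FVB pairs of all 4 marks and assume that B6 varies like them, which these samples cannot test, so they describe these preparations under that assumption. Of 25985 windows edgeR then called 9509 for H3K4me1 (5913 higher in B6, 3596 lower), 4166 for H3K4me3 (3222, 944), 20614 for H3K27me3 (11980, 8634) and 12640 for H3K9me3 (10860, 1780). Library size moved the medians by −0.21, −0.16, −0.36 and −0.54 and the splits to 3789 and 8874, 1864 and 2424, 7327 and 12856, and 4228 and 12731. With 1 FVB preparation left out no residual degrees of freedom remained, so there was no test. DESeq2 called 5607 windows in H3K4me1, and the fit with plates as libraries 6009 in H3K4me1 and 2000 in H3K4me3.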

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

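Apart from the tests on the low number of cuts per cell in H3K27me3 cluster 6 and on a flat background in H3K4me1 cluster 3, the tests in this part were chosen after the results were seen.

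Among 36 groups of 4 plates, 2 held a plate far from the others, and chance alone gives about 1 in 20 groups. In B6 H3K4me1 plate m1-2 the well with most cuts held 9.9% of the plate's cuts, against 1.2%, 1.5% and 2.1% in the other plates. In B6 H3K9me3 plate m1-4 5.45% of counts had no coordinate, against 6.06%, 6.1% and 6.14%. Counts without a coordinate reached 13.66% of a B6 plate and were not used in any comparison. Wells under the minimum of cuts, 2466 in number, held 409394 cuts (0.243% of all), which no comparison used either.

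The concentration of cuts in B cell-like cells lay above that of the other cells in every preparation for H3K4me1, by 6.26 points in cluster 1 and 6.34 points in cluster 6, and below it in every preparation for H3K4me3, with a difference of −2.35 points in cluster 1. The difference between the marks was not tested.

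Windows far higher in B6 for H3K4me1 were also higher for H3K9me3, which otherwise runs against it. In the 8 windows at least 4 times higher in B6 for H3K4me1, the median log2 ratio of B6 over FVB was 4.2 for H3K9me3. Cuts that accumulate with any antibody would give this. Medians of 4.12 for H3K4me3 and 2.33 for H3K27me3 count for little here, since both run with H3K4me1, whose 3.79 was fixed by the choice. The 8 ratios for H3K9me3 formed a low set (1.1, 1.2, 1.5 and 2.09) and a high set (6.31, 7.34, 7.54 and 7.93), so the median describes neither. The 27 windows at least 2 times higher in B6 for all 4 marks held 3.21% of B6 H3K9me3 cuts against 0.0454% and 0.0476% in FVB, and 0.785%, 1.16% and 0.451% of B6 H3K4me1, H3K4me3 and H3K27me3 cuts. They were chosen for being higher in B6, so the direction of the share was fixed in advance and the share decides nothing. Reads of repeats kept in one set of tables and removed from the other, or copy number of the strain, stay open. These cannot be told apart, because strain, age and tables change together, and a biological difference by strain or age stays open and untested.

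H3K27me3 cluster 6 held shallow cells with more cuts at Hox, developmental factor and erythroid windows. Its developmental factor windows stood 1.05 above the median window (log2; 1.11, 1.37 and 0.68 in FVB m1, FVB m2 and B6 m1). These windows are part of the pattern itself, so the value decides nothing. Against the 738 cells of similar depth the value was 0.19 (0.09, 0.67 and −0.18). The preparations disagreed there, so neither open chromatin nor the low number of cuts per cell alone could be excluded. The design gives no group for this cluster, and no biological explanation was tested.

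H3K4me1 cluster 3 was lower at the windows of every cell type list with the preset correlation, while 0 of 18 lists passed with an estimated one. Across autosomal windows its log2 fold fell with the level in the remaining cells, with a Spearman rho of −0.605 (−0.527, −0.51 and −0.779 by preparation) against means of −0.347 to 0.346 in the other clusters, where cluster 5 reached −0.567 in B6 m1, consistent with a flat background of cuts added to cells of other types. The median log2 fold of the 9 cell type lists was −0.2 (−0.16, −0.16 and −0.28), which lay at the limit set for 2 or more cells in 1 well, so this stays open. The design gives no group for this cluster, and no biological explanation was tested.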

How the results depend on the processing

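The tests that left out wells above 10 times the 95th percentile, the relations between marks with 1 replicate left out, and all counts over other assignments of the samples, were chosen after the results were seen.

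Counts by cluster moved under more alternatives than counts by mark. All 4 counts by mark in marrow and all 4 in K562 stayed within 1.5 times of the reported count with DESeq2, library size alone, no filter, shifted windows, at least 1000 cuts, no minimum, autosomes only, a replicate block and without the wells of extreme depth, and in marrow also with plates as libraries. The 21 cluster counts stayed within 1.5 times under library size alone. Where no cause is named below, the cause was not tested.

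A replicate block by preparation or replicate number moved none of the counts by mark by over 1.5 times. Samples of the same number correlated on average (mean r of deviations from the mark means) at 0.186, 0.126 and 0.278 in FVB m1, FVB m2 and B6 m1 and at −0.109, 0.0383 and 0.146 in K562 replicates 1 to 3, and not every pair exceeded 0.1. With other numbers the marrow means were −0.0354, −0.0151 and −0.213. The correlations thus do not settle whether the numbers pair the samples, and the labels name a preparation across the 4 marks without saying that it is 1 animal. Clusters and their remaining cells come from the same plates and had the block. With no replicate block H3K4me1 clusters 1, 2, 3, 4, 6, 7 and 8 gave 1819, 3560, 287, 232, 498, 355 and 64 windows, and H3K4me3 clusters 1 to 3 gave 820, 989 and 11. H3K27me3 clusters 1, 2, 4, 5 and 6 then gave 0, 2, 0, 0 and 345 in edgeR, with 287, 2561 and 4019 windows at an unadjusted p under 0.05 in clusters 1, 4 and 5. H3K9me3 clusters 1, 2, 3 and 5 gave 0 each, with 11712, 2569, 3183 and 7920 at an unadjusted p under 0.05. DESeq2 was not run without the block. Lists past the threshold became 6 in H3K4me1 cluster 7 and 1 in H3K4me3 cluster 3.

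DESeq2 gave 1691, 2650, 1881, 135, 1993, 647, 143 and 40 windows in H3K4me1 clusters 1 to 8, 223, 578, 3 and 171 in H3K4me3 clusters 1 to 4, 1853, 2681, 3249, 5396 and 458 in H3K27me3 clusters 1, 2, 4, 5 and 6, and 7025, 557, 42 and 3755 in H3K9me3 clusters 1, 2, 3 and 5. For B6 against FVB it gave 5607 in H3K4me1, and plates as libraries gave 6009 in H3K4me1 and 2000 in H3K4me3.

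Leaving out samples lowers the number tested, and these fits were run in edgeR alone. Without replicate FVB m1 the marrow counts were 12306, 8473 and 8564 for H3K4me1, H3K4me3 and H3K27me3, and without replicate FVB m2 11395 for H3K4me3. K562 H3K4me3 ranged from 7932 to 15227 with 1 replicate left out. Without FVB m1 the cluster counts were 828, 1221 and 527 (H3K4me1 clusters 4, 6, 7), 1703, 45 and 721 (H3K4me3 clusters 2, 3, 4), 1730, 4831, 414, 3876 and 345 (H3K27me3 clusters 1, 2, 4, 5, 6) and 9858, 1387, 449 and 1343 (H3K9me3 clusters 1, 2, 3, 5). Without FVB m2 they were 2539 and 736 (H3K4me1 clusters 3, 4), 39 (H3K4me3 cluster 3), 3771, 1823, 3018 and 295 (H3K27me3 clusters 2, 4, 5, 6) and 2171, 813 and 1309 (H3K9me3 clusters 2, 3, 5). Without B6 m1 they were 1745, 1964, 2056, 437, 2966, 477, 57 and 0 (H3K4me1 clusters 1 to 8), 720, 781, 0 and 3 (H3K4me3 clusters 1 to 4), 2225 and 0 (H3K27me3 clusters 1, 6) and 472 and 24 (H3K9me3 clusters 2, 3). The 3 counts of 0 went with 1899, 800 and 809 windows at an unadjusted p under 0.05. For B6 against FVB no such test was possible.

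Using all cuts, which doubles the depth but tests clusters on the cuts that formed them, gave 9045, 2939, 7860, 3968, 2479 and 1222 in H3K4me1 clusters 3 to 8, 3425, 4149, 291 and 2804 in H3K4me3 clusters 1 to 4, 6727 and 2419 in H3K27me3 clusters 1 and 6, and 8765, 4599 and 12130 in H3K9me3 clusters 2, 3 and 5. Plates as libraries with plate as block gave 2890 in H3K4me1 cluster 3, 653 in H3K4me3 cluster 4, 606 and 3456 in H3K27me3 clusters 1 and 6, and 2359 and 1722 in H3K9me3 clusters 2 and 5. Without the filter H3K4me3 cluster 3 gave 38. With an estimated correlation 0 lists passed in camera in all 25 contrasts, and the lowest adjusted p was 0.193.

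With the top 5% of windows the shares of cuts were 15.7%, 18.2%, 9.4% and 14.9% in marrow and 19.8%, 31.1%, 12.8% and 17% in K562, and with the top 20% they were 46.1%, 50.4%, 32.3% and 46.4%, and 53.3%, 67.6%, 40.1% and 51.7%, a change built into the setting. Cluster differences at 5% were 4.73 and 6.39 (H3K4me1 clusters 1, 2), −1.5 and 2.17 (H3K4me3 clusters 1, 2), 1.53, 2.52 and 7.96 (H3K27me3 clusters 2, 4, 6) and −4.51, 2.23 and 5.58 (H3K9me3 clusters 1, 3, 5). At 20% they were 7.67, 13.2, −11.1 and, turned in direction, 0.373 (H3K4me1 clusters 1 to 4), 5.19 and 0.729 (H3K4me3 clusters 2, 4), 4.76, 6.61 and 14.1 (H3K27me3 clusters 2, 4, 6) and −12.4, 4.95, 5.82 and 15.4 (H3K9me3 clusters 1, 2, 3, 5). Without thinning they were 8.6 and 0.141 (H3K4me1 clusters 2, 8), −2.34, turned, and 0.343 (H3K4me3 clusters 3, 4), 3.79 and 4.93 (H3K27me3 clusters 2, 4) and 2.81 (H3K9me3 cluster 3). With windows ranked once per preparation they were 2.81, 6.69, −3.04 (turned) and 3.59 (H3K4me1 clusters 1, 2, 5, 6), 2.68, −0.866 and −1.19, the last pair turned (H3K4me3 clusters 2, 3, 4), and −6.55 and 1.91 (H3K27me3 clusters 5, 6). Without B6 m1 the differences turned to 0.372 in H3K4me1 cluster 4 and −0.696 in H3K4me3 cluster 3.

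Without B6 m1 rho of H3K27me3 with H3K9me3 in marrow was −0.206, and in K562 it was −0.142 without replicate 1 and −0.359 without replicate 2. On autosomes only, rho with H3K9me3 in marrow was −0.666 for H3K4me1 and −0.616 for H3K4me3, and with at least 1000 cuts per cell rho of H3K4me1 with H3K9me3 in K562 was −0.383. Leiden at resolution 0.25 gave 5, 3 and 3 clusters for H3K4me1, H3K4me3 and H3K9me3, and at resolution 1.0 gave 13 and 12 for H3K27me3 and H3K9me3. Memberships moved more, with an adjusted Rand index from 0.242 (H3K9me3, window mean over all preparations) to 0.863 (H3K4me1, resolution 1.0).

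Over 40 drawn assignments of the 12 marrow libraries to marks, 2 gave at least the real count of 18957 windows for H3K4me1 (highest other 22328), 1 for H3K4me3 (17636, highest other 15147), 3 for H3K27me3 (13606, highest other 22296) and 1 for H3K9me3 (23347, highest other 18506), the real one included. By these draws the share of assignments lay under 0.05 for H3K4me3 and H3K9me3 and not for H3K4me1 and H3K27me3. For the latter the assignments with more windows kept the 3 H3K9me3 libraries together, a structure of the samples. A draw that repeated the real group of a mark was skipped, so no other draw could keep these 3 libraries together for H3K9me3. The H3K9me3 result was thus partly fixed in advance. In K562 1 of 40 reached the real count for each mark, the real one. The highest others were 14510, 8921, 14976 and 11279 windows. These draws did not keep 1 library of each preparation or replicate in every group. Over 40 that did, the real one included, 1 reached the real marrow count for H3K4me1, H3K4me3 and H3K9me3 (highest others 11100, 4500 and 21663). For H3K27me3 3 did (highest other 14240), so chance of this kind cannot be excluded there. In K562 1 of 40 reached the real count for each mark, with highest others of 3697, 5308, 11099 and 14410. Where 1 of 40 reached the real count, only the real assignment did. This is the smallest share that 40 assignments can give, and it was not adjusted over the marks, so the draws alone do not exclude chance. For the clusters 10 splits are too few for a share under 0.05: the real split gave 24884, 6411, 33147 and 27530 windows summed over clusters of H3K4me1, H3K4me3, H3K27me3 and H3K9me3, and the highest other 131, 9, 226 and 0, so that 1 of 10 reached the real count in each.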

Other observations

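All tests and loci in this part were chosen after the results were seen.

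The immunoglobulin kappa locus separated the B cell-like clusters from the other named ones, and the heavy chain locus did not. At the immunoglobulin kappa locus (6:67555636 to 70726754) 31 of 31 windows were higher in the B cell-like cluster 1 of H3K4me1, with a median log2 fold of 2.38 relative to all windows, and 18 in the B cell-like cluster 6 (0.81). There 31 windows were lower in granulocyte-like cluster 2 (−2.36), 29 in erythroid-like cluster 5 (−1.54), 29 in monocyte and macrophage-like cluster 7 (−2.15) and 27 in T and NK cell-like cluster 8 (−2.09). For H3K4me3 31 windows were higher in B cell-like cluster 1 (2.13) and 30 lower in granulocyte-like cluster 2. At the heavy chain locus (12:113258768 to 116009954) H3K4me1 was higher in 14 of 27 windows in cluster 1 (0.64), higher in 12 and lower in 3 in granulocyte-like cluster 2 (0.37), and lower in 19 in cluster 5 (−1.49). In B cell-like cluster 6 it was higher in 1 and lower in 4 (−0.39). In T and NK cell-like cluster 8, 4 of 15 windows of the T cell receptor alpha locus (14:52427967 to 54224198) were higher (1.13), and 2 of 7 of the beta locus (6:40891296 to 41558371; 0.45).

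The repressive marks also split at the kappa locus. H3K27me3 was higher in 31 windows in cluster 2 (1.35), where Pax5 and Ebf1 were lower and Cd79a higher, and lower in 28 in cluster 4 (−1.17), where Pax5 was higher. H3K9me3 was lower in 27 windows in cluster 1 (−0.82) and higher in 26 in cluster 2 (0.56) and 22 in cluster 5 (1.09). These are different cells from those of the active marks, and the clusters carry no names.

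Clusters of the same name in H3K4me1 and H3K4me3 may hold cells of the same type in part. Cells of the same type separated in both marks would give log2 folds across windows that correlate higher within a name than between names. This was so for 4 of the 4 names, with the smallest gap to another name at 0.118. Spearman rho across windows was 0.665 for the granulocyte-like and 0.712 for the erythroid-like clusters, with 0.562 for the B cell-like clusters numbered 1 and 0.394 for the monocyte and macrophage-like clusters. Markers from the same lists gave the names in both marks, so the test is not independent of them. The shares of cells under a name differed between the marks. Granulocyte-like cells were 7.28%, 14.4% and 22.3% in FVB m1, FVB m2 and B6 m1 for H3K4me1 against 35.9%, 33.8% and 38.5% for H3K4me3, and B cell-like cells 30.9%, 22.5% and 25.1% against 47.4%, 49.9% and 38.9%. Of H3K4me1 cells 32.4%, 38.3% and 28.7% carried no name. The correlations thus speak for related windows and not for the same set of cells under each name.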
